A study of Homo sapiens with 12 samples.

How the data were processed

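RNA abundance was measured on 12 arrays of MDA-MB-231 cells, an established human line of triple-negative breast cancer. Per the labels' protocols, cells were transfected for 48 h with an oligonucleotide at 50 nM, total RNA was extracted, and biotin-labelled cDNA was made from 100 ng of RNA for hybridisation to Affymetrix arrays. The labels name 4 groups of 3 arrays: a negative control oligonucleotide, a mimic of miR-183-5p with its reference ends (called the archetype here, as in the series description), and mimics of 2 isomiRs, which are forms of the same microRNA with shifted ends. The isomiR with both ends moved by -2 nucleotides is called minus2 here. The series description writes its ends as 2 and -2 in 1 place, whereas the labels give -2 for both, and the labels with their sequence were followed. Likewise, the isomiR with both ends moved by 2 nucleotides is called plus2. Nothing in the labels says that the 3 arrays of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

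The deposited values are log2 signals, 1 column per array and 1 row per feature. Affymetrix Expression Console 1.4.1 and RMA are named in the submitters' processing notes, without their role, settings or order. RMA corrects background, quantile-normalises and summarises probes, and settings such as a correction for GC content were not given in the sources used here. The log2 scale is not stated in words. It was inferred from the values, which lay between 1.79 and 19.9 with array medians between 4.73 and 4.80. The arrays' distributions were close but not identical. Each array was hybridised from the same amount of RNA, so a change in total RNA per cell was not measured.

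Of 70523 features, 2995 that were not transcript clusters were left out. Of the 67528 transcript clusters, 23781 carried 1 gene symbol in the platform annotation given for this work, 1543 carried several and 42204 carried none. Clusters with several symbols or none were not named. Symbols were updated through gene identifiers and synonyms in a table of human RefSeq genes (GRCh38.p14), used for names only, which changed 247 of them, and 22407 of the resulting 22411 genes were in that table. For the 528 genes with more than 1 cluster, the cluster with the highest mean signal was used. Genes in the upper part of the distribution of mean signal were tested, above a log2 signal of 4.54, which left 14940 genes, 12215 of them protein-coding. No column of per-sample values was left unused. No coordinates are given because the genome build of the files was not given in the sources used here.

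Group means were fitted over all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), so that the 4 groups shared an estimate of the spread with 8 residual degrees of freedom. The 3 mimics were each compared with control and with each other, and the mean of the mimics with control, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05 on the adjusted p. A moderated F test asked for any difference among the 4 groups. A gene is said to have risen, fallen or changed only where it passed that threshold. Errors of log2 fold changes are standard errors from limma, and errors of signals are SDs of 3 arrays. An exact permutation test of 3 against 3 arrays cannot give a two-sided p below 0.1, so single genes were not tested that way.

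Before the data were examined, 25 gene lists were fixed, among them markers of luminal breast cells, white blood cells and fibroblasts. They were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 25 lists of a comparison. Camera with a correlation estimated from these arrays, and fry, were run as alternatives. Within lists, members were counted as called over all genes tested and as adjusted over the list alone. Named genes were chosen by a rule set in advance. Against control these are the 10 largest called changes in each direction in which the 3 treated arrays lay on 1 side of all 3 control arrays, and between mimics the 5 largest. For each list the rule adds up to 4 called members with the largest changes, and it makes every reported miR-183-5p target eligible. Symbols of uncharacterised loci, small RNAs and antisense transcripts were passed over. The lists were written from general knowledge, and the list of reported targets holds genes named as targets in earlier work on miR-183-5p.

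The fits were tested on simulated data drawn from the real gene means and residual SDs. In each comparison with control 200 of 14940 genes were changed, and the other tested members of the interferon response list were raised by 0.3. This is a much smaller share than was called in the real data, so the rates below may not carry over to it. At a log2 change of 1 the share recovered was 96.9% for the archetype, 98.5% for minus2 and 96.8% for plus2. At 0.3 it was 62.5%, 59.6% and 56.5%. False calls made up 7.29%, 6.06% and 1.10% of all calls in those 3 simulations. Each rate comes from 1 draw in which all groups had the same spread per gene. The real plus2 arrays had a larger median SD (0.0827, against 0.0641 in control), so the rate for plus2 in particular may not carry over. Overlap between comparisons that share the control arrays was simulated 100 times with unchanged groups, and 100 times with each mimic's estimated effects dealt at random to genes of a like residual SD.

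Alternatives covered the filter on signal, the choice of cluster per gene, unnamed clusters, array centring, a further quantile normalisation, array weights, trended and robust eBayes, fits on the arrays of 2 groups alone, other thresholds, a block for the replicate number, and leaving out each array in turn. A planned test of seed-matched sites in 3′ untranslated regions was not run, because transcript sequences were not used here. Arrays measure long RNA, so the transfected mimics themselves were not measured. The number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9.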

Results

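Gene expression was measured in MDA-MB-231 breast cancer cells 48 h after transfection with 50 nM of a negative control oligonucleotide, of a miR-183-5p mimic (the archetype), or of mimics of 2 isomiRs of the same microRNA. Each group had 3 arrays. The 3 mimics are 22 nt long and share 18 nt. The minus2 mimic has the sequence TGTATGGCACTGGTAGAATTCA and the plus2 mimic TGGCACTGGTAGAATTCACTGT, written as DNA, and the archetype between them reads TATGGCACTGGTAGAATTCACT when derived from their overlap. The shift moves the seed, nucleotides 2 to 8 from the 5′ end, which is ATGGCAC in the archetype, GTATGGC in minus2 and GGCACTG in plus2. The comparisons address which transcripts respond to each form, and whether the forms of this microRNA act on the same ones.

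Replicate arrays of a group correlated with Pearson's r across genes between 0.997 and 0.999, and genes are not independent replicates. The median SD between replicates was 0.0641 log2 units in control, 0.0607 with the archetype, 0.0576 with minus2 and 0.0827 with plus2. No pair of arrays held identical values. In a principal component analysis of the tested genes, component 1 (37.8% of the variance) placed minus2 and plus2 at opposite ends and component 2 (22.6%) set control apart from all mimics. Of 14940 genes tested, 7726 (51.7%) differed among the 4 groups by limma's moderated F test with Benjamini-Hochberg adjustment.

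**Figure D1:**
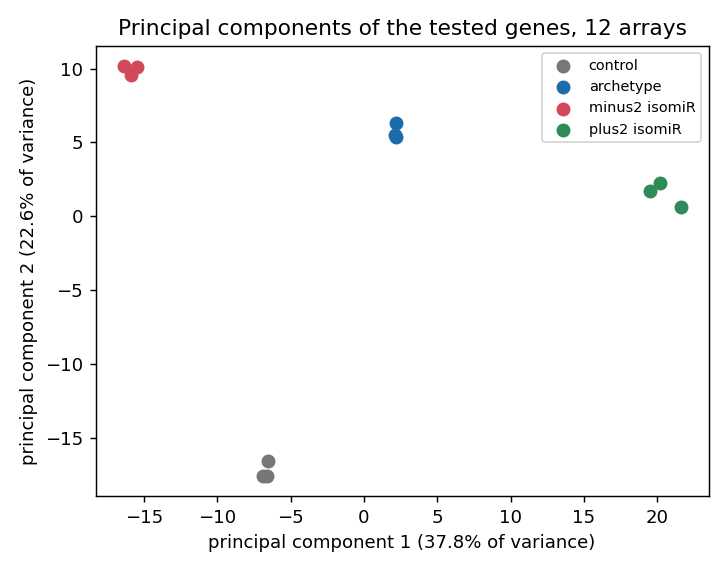
Principal component 1 (x axis, 37.8% of the variance) and component 2 (y axis, 22.6%) of the tested genes, 1 point per array and 3 arrays per group. The minus2 arrays lie between -16.4 and -15.5 on component 1, the plus2 arrays between 19.5 and 21.6, and the control arrays below -16 on component 2.

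**Figure D2:**
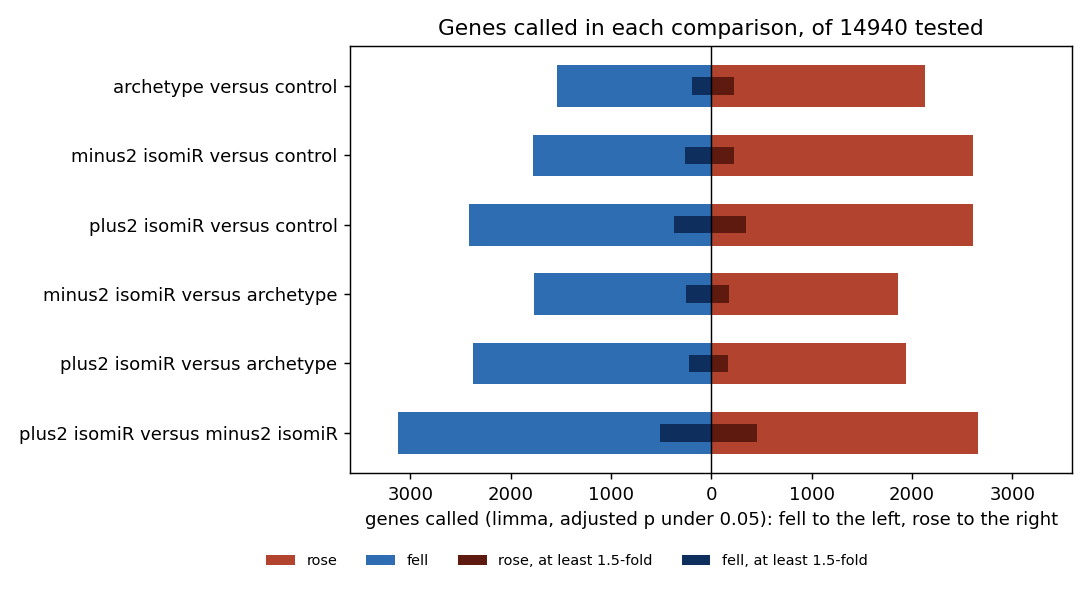
Genes called by limma at an adjusted p under 0.05 in each comparison (wide bars) and those among them that changed at least 1.5-fold (narrow bars), with falls to the left and rises to the right on a linear axis. The largest number of calls, 5787, was between the plus2 and minus2 isomiRs.

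With the archetype, ITGB1, which encodes the integrin beta-1 subunit, fell from a log2 signal of 15.70 ± 0.03 (SD, n = 3) in control to 13.76 ± 0.03, a change of -1.94 ± 0.04 (SE). DKK1, a secreted Wnt antagonist, rose by 2.56 ± 0.08, the largest rise, and the tight junction gene CLDN1 rose by 2.06 ± 0.09. STC1, which encodes the secreted glycoprotein stanniocalcin-1, fell from 12.71 ± 0.03 to 10.71 ± 0.04 (SD), and GNG5, a G protein gamma subunit, changed by -2.17 ± 0.06. In all, 3669 of 14940 genes were called, of which 2134 rose and 1535 fell, and 222 rose and 192 fell at least 1.5-fold. The excess of rises depended on the scaling, with 1890 rises and 1885 falls after centring the arrays on their medians and 2013 and 1843 after a further quantile normalisation.

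The other largest rises with the archetype were those of ANKRD1 (1.77 ± 0.10 log2), the carboxypeptidase gene CPA4 (1.76 ± 0.17), the ligand gene TGFB2 (1.73 ± 0.05), the centriole gene C2CD3 (1.66 ± 0.06), PSG1 (1.58 ± 0.12), the circadian repressor CRY1 (1.52 ± 0.08), the endothelin gene EDN1 (2.83-fold) and PSG9 (1.44 ± 0.10). Adjusted p was at most 1.9e-05 among these 10 genes (limma). The other largest falls were those of EI24 (-2.16 ± 0.06), GNG5B (-2.04 ± 0.15), LAPTM5 (-1.88 ± 0.08), the calcium pump gene ATP2B4 (-1.75 ± 0.09), the collagen crosslinking enzyme LOX (-1.64 ± 0.08), EMP1 (-1.59 ± 0.08) and the translocon gene TRAM1 (-1.49 ± 0.05), with adjusted p at most 2.1e-06. GNG5 and GNG5B are near-identical copies, as are members of the PSG family, and their signals may not be separable on these arrays. PSG1 had a control signal of 4.81, near the lower limit of the tested genes, so its change is measured against a signal not shown to be above background.

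Among 19 tested genes reported as miR-183-5p targets, 14 fell and 2 rose with the archetype (15 and 2 adjusted over the list alone). ITGB1 fell most, followed by the PP2A catalytic subunit PPP2CA (-0.97 ± 0.04), the mitochondrial isocitrate dehydrogenase IDH2 (-0.95 ± 0.05) and the kinesin KIF2A (-0.93 ± 0.05). The Wnt co-receptor LRP6 (-0.74 ± 0.04), SMAD4 (-0.52 ± 0.06) and RB1 (-0.45 ± 0.06) also fell, while BTRC rose by 0.36 ± 0.04 and EZR (-0.11 ± 0.06) and FOXO1 (-0.21 ± 0.09) did not pass. The list's camera adjusted p was 1.6e-11, and adjusted p = 0.028 with an estimated correlation.

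Of 23 tested genes of hypoxia and glycolysis, 17 fell and 1 rose with the archetype (19 and 1 adjusted over the list alone). PFKFB4 (-0.90 ± 0.07), the angiogenic factor VEGFA (-0.78 ± 0.04) and the collagen hydroxylase P4HA1 (-0.50 ± 0.05) fell, and the glucose transporter SLC2A3 rose by 0.69 ± 0.11. The camera adjusted p was 3.9e-10, and adjusted p = 0.028 with an estimated correlation. Of 29 genes of G2/M and mitosis, 15 fell and none rose (17 and 0 adjusted over the list alone), with the mitotic kinase PLK1 at -1.24 ± 0.07, CENPE at -0.57 ± 0.10 and DLGAP5 at -0.52 ± 0.05 (camera adjusted p = 2.8e-07, adjusted p = 0.31 with an estimated correlation). Of 28 genes of G1/S and DNA replication, 8 rose and none fell (9 and 0 adjusted over the list alone), among them the transcription factor E2F1 (0.49 ± 0.06) and the licensing factor CDC6 (0.45 ± 0.07). Camera gave an adjusted p of 0.013, and adjusted p = 0.91 with an estimated correlation.

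Mesenchymal genes fell with the archetype in 8 of 16 cases and rose in 2 (9 and 2 adjusted over the list alone), led by LOX and by the matrix genes TNC (-0.89 ± 0.04) and MMP14 (-0.61 ± 0.05) and the repressor ZEB1 (-0.53 ± 0.04). Camera gave an adjusted p of 0.00034, and adjusted p = 0.057 with an estimated correlation. In the actin cytoskeleton and focal adhesion list 11 of 34 fell and 3 rose (12 and 3 alone), with ITGB1 at -1.94 ± 0.04 and moesin, MSN, at -0.84 ± 0.04 (camera adjusted p = 0.0034, adjusted p = 0.56 with an estimated correlation). The TGF-beta and SMAD list had 12 falls and 4 rises in 22 genes (15 and 4 alone). ID1 changed by -1.46 ± 0.11, against rises of TGFB2 (1.73 ± 0.05), THBS1 (1.10 ± 0.09) and CCN1 (0.98 ± 0.07). The list's camera adjusted p was 0.0022, and adjusted p = 0.21 with an estimated correlation. Genes of MAPK signalling and the immediate-early response fell in 13 of 22 cases and rose in 2 (13 and 3 alone), with FOSL2 at -0.56 ± 0.07 (camera adjusted p = 9.2e-05, adjusted p = 0.28 with an estimated correlation). Interferon response genes fell in 6 of 29 cases (8 alone), among them the RNA sensor RIGI (-0.67 ± 0.05) and OAS3 (-0.49 ± 0.05), with a camera adjusted p of 0.0020, and adjusted p = 0.41 with an estimated correlation.

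The 11 tested white blood cell markers gave 4 falls and no rise with the archetype (4 and 1 adjusted over the list alone), led by LAPTM5, LCP1 (-0.48 ± 0.08) and CD68 (-0.32 ± 0.08), with a camera adjusted p of 0.017, and adjusted p = 0.31 with an estimated correlation. LAPTM5, a lysosomal protein best known from blood cells, fell with every mimic, by 1.53 with minus2 and by 1.05 with plus2. Luminal markers (4 rose, 2 fell of 11, camera adjusted p = 0.91) and fibroblast markers (0 rose, 1 fell of 5, adjusted p = 0.67) were not called as lists with the archetype. Lists of the microRNA pathway, p53 targets, unfolded protein response, cholesterol biosynthesis, epithelial genes, Wnt, PI3K and FOXO signalling, apoptosis, DNA repair, extracellular matrix, oxidative phosphorylation, ribosomal proteins and NF-kB were not called with the archetype either, at camera adjusted p of 0.19 or more. The p53 list had a median of -0.01, a mean of 0.04 and a test that pointed down, and the Wnt list a median of 0.01, a mean of 0.05 and a test that pointed down.

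With minus2, TMEM109 fell from a log2 signal of 11.46 ± 0.05 (SD, n = 3) to 9.08 ± 0.11, a change of -2.38 ± 0.07 (SE). NSA2, a ribosome assembly factor, fell by 2.25 and the deubiquitinase gene UCHL3 from 11.66 ± 0.04 to 9.42 ± 0.07. CXCL8, which encodes the chemokine interleukin-8, changed by -1.94 ± 0.06, and ITGB1 by -1.59 ± 0.04. CPA4 rose by 1.76 ± 0.17 and DKK1 by 1.56 ± 0.08. The comparison called 4388 of 14940 genes, of which 2612 rose and 1776 fell, whereas at 1.5-fold or more 226 rose and 263 fell, so the share of rises was 59.5% without a fold limit and 46.2% with it. Without a fold limit that share was 50.2% after centring the arrays and 53.3% after a further quantile normalisation.

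Other large falls with minus2 were those of the phosphodiesterase gene GDE1 (-2.12 ± 0.11), the phosphatase gene PTP4A1 (-1.92 ± 0.07), PAQR5 (-1.87 ± 0.11), HPS3 (-1.76 ± 0.07) and the ferritin autophagy receptor NCOA4 (-1.68 ± 0.05). Other large rises were those of the mitochondrial phosphatase PTPMT1 (1.48 ± 0.05), the PP2A scaffold PPP2R1B (1.33 ± 0.05), CRY1 (1.31 ± 0.08), ARRDC4 (1.30 ± 0.08), the desmosome gene PKP2 (1.29 ± 0.07), the signal recognition particle receptor SRPRA (1.20 ± 0.04), CEMIP2 (1.19 ± 0.05) and the transcription factor NFYA (1.18 ± 0.07). Adjusted p was at most 1.8e-05 among the 10 rises and 3.3e-07 among the 10 falls (limma, Benjamini-Hochberg).

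In the list of NF-kB and inflammatory cytokine genes, 13 of 19 fell and none rose with minus2 (15 and 1 adjusted over the list alone). Besides CXCL8 these included the chemokine CXCL1 (-1.21 ± 0.09), the adhesion molecule ICAM1 (-0.92 ± 0.12) and TNFAIP2 (-0.85 ± 0.09). Camera gave an adjusted p of 1.3e-08, and adjusted p = 0.11 with an estimated correlation. Of the 19 reported miR-183-5p targets 10 fell and 1 rose (10 and 1 alone), with LRP6 at -0.77 ± 0.04, PPP2CB at -0.73 ± 0.04 and KIF2A at -0.51 ± 0.05 (camera adjusted p = 0.00037, adjusted p = 0.23 with an estimated correlation). The gene BNIP3L rose by 0.24 ± 0.04, and TAOK1 (0.04 ± 0.06) and MTA1 (-0.04 ± 0.04) did not pass.

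G2/M and mitosis genes fell in 16 of 29 cases with minus2 and none rose (16 and 0 adjusted over the list alone), with KIF23 at -0.62 ± 0.08 and HMMR at -0.46 ± 0.09 (camera adjusted p = 4.8e-08, adjusted p = 0.36 with an estimated correlation). Interferon response genes fell in 12 of 29 cases and none rose (13 and 0 alone), with DDX60 at -0.76 ± 0.05 and IFIT3 at -0.63 ± 0.07 (camera adjusted p = 0.0011, adjusted p = 0.41 with an estimated correlation). Mesenchymal genes fell in 9 of 16 cases and 1 rose (10 and 1 alone), with LOX at -1.03 ± 0.08 and CD44 at -0.45 ± 0.05 (camera adjusted p = 0.00017, adjusted p = 0.11 with an estimated correlation). In the TGF-beta and SMAD list 13 of 22 fell and 5 rose (13 and 5 alone), with the receptor TGFBR2 at -1.16 ± 0.04 and THBS1 at 1.13 ± 0.09 (camera adjusted p = 0.0037, adjusted p = 0.25 with an estimated correlation). MAPK and immediate-early genes fell in 7 of 22 cases and 1 rose (7 and 1 alone), led by FOSL2 at -0.91 ± 0.07 (camera adjusted p = 0.0015, adjusted p = 0.41 with an estimated correlation). Extracellular matrix genes fell in 5 of 18 cases and 1 rose (7 and 2 alone), with TIMP3 at -0.78 ± 0.08 and COL12A1 at 0.54 ± 0.06 (camera adjusted p = 0.036, adjusted p = 0.53 with an estimated correlation). That call was lost without control replicate 1 (adjusted p = 0.057) and without minus2 replicate 3 (adjusted p = 0.062).

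Hypoxia and glycolysis genes were not called as a list with minus2 (5 rose, 5 fell of 23, or 8 and 6 adjusted over the list alone, camera adjusted p = 0.87), with a median of -0.03 and a mean of 0.04. Neither were markers of white blood cells (1 rose, 3 fell of 11, adjusted p = 0.24), luminal cells (1 rose, 1 fell of 11, adjusted p = 0.86, median 0.02 and mean -0.02) or fibroblasts (0 called of 5, adjusted p = 0.87). Among genes of the microRNA pathway DICER1 rose by 0.52 ± 0.05, in a list with 4 rises and 2 falls of 10 (adjusted p = 0.64).

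With plus2, VAMP3, a vesicle SNARE, fell from a log2 signal of 13.10 ± 0.07 (SD, n = 3) to 10.74 ± 0.07, and moesin, MSN, which links actin to the membrane, from 15.31 ± 0.05 to 13.10 ± 0.03. CXCL8 rose by 2.02 ± 0.06 (SE), opposite to its fall with minus2. TGFB2 rose by 2.21 ± 0.05, CPA4 by 2.20 ± 0.17 and DKK1 by 2.19 ± 0.08. ITGB1 changed by -1.57 ± 0.04. In this comparison 5020 of 14940 genes were called, 2605 up and 2415 down, with 344 up and 377 down at least 1.5-fold. After centring the arrays the majority turned, with 2488 up and 2687 down. Fitted on the arrays of the 2 groups compared alone, plus2 had 3873 calls and minus2 4497, and with array weights 4654 and 5088. Which isomiR had more calls against control thus depended on the fit.

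Other large rises with plus2 were those of CLDN1 (2.04 ± 0.09), ACTBL2 (1.89 ± 0.15), EDN1 (1.87 ± 0.12), PLEKHS1 (1.81 ± 0.08), ANKRD1 (3.49-fold) and CRY1 (1.65 ± 0.08). Other large falls were those of EI24 (-2.04 ± 0.06), GINM1 (-1.77 ± 0.09), TMBIM6 (-1.71 ± 0.04), the actin regulator MICAL2 (-1.70 ± 0.04), CPNE3 (-1.70 ± 0.05), the EGF receptor ligand HBEGF (-1.65 ± 0.06), cyclin K, CCNK (-1.61 ± 0.05), and EMP1 (-1.59 ± 0.08). ACTBL2 lay at 6.59 with plus2, but in control and with the archetype near the lower limit of the tested genes, where a signal is not shown to be above background. Adjusted p was at most 2.8e-06 among the 10 rises and 1.0e-07 among the 10 falls (limma, Benjamini-Hochberg).

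Of 34 genes of the actin cytoskeleton and focal adhesion, 18 fell and 3 rose with plus2 (20 and 4 adjusted over the list alone), with MSN followed by ITGB1, talin, TLN1 (-0.92 ± 0.06) and paxillin, PXN (-0.64 ± 0.06). Camera gave an adjusted p of 0.00023, and adjusted p = 0.56 with an estimated correlation. Mesenchymal genes fell in 9 of 16 cases and 3 rose (10 and 4 alone), with LOX at -1.31 ± 0.08 and the integrin gene ITGA5 at -1.07 ± 0.08 (camera adjusted p = 0.015, adjusted p = 0.56 with an estimated correlation). MAPK and immediate-early genes fell in 10 of 22 cases and 1 rose (10 and 1 alone), with FOSL1 at -1.42 ± 0.07, ETV4 at -0.98 ± 0.07 and EGR1 at 0.82 ± 0.09 (camera adjusted p = 0.0023, adjusted p = 0.56 with an estimated correlation). Ribosomal protein genes fell in 8 of 17 cases and none rose (9 and 0 alone), by small amounts such as -0.24 ± 0.04 for RPS6 (camera adjusted p = 0.0023, adjusted p = 0.56 with an estimated correlation).

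The 19 reported miR-183-5p targets gave 8 falls and 4 rises with plus2 (8 and 5 adjusted over the list alone), and the list was not called (camera adjusted p = 0.16). MTA1 (-0.62 ± 0.04) and IRS1 (-0.56 ± 0.09) fell with ITGB1, whereas LRP6 rose by 0.28 ± 0.04 and SMAD4 and PPP2CB were among the 7 that did not pass. The NF-kB list had 7 rises and 2 falls of 19 (7 and 2 alone) and was not called either (camera adjusted p = 0.090), although TNFAIP3 (0.89 ± 0.09), CCL2 (0.84 ± 0.15) and IL6 (0.58 ± 0.08) rose. CCL2 lay at 4.69 in control, near the same limit. E-cadherin, CDH1, an epithelial adhesion gene, rose by 1.14 ± 0.08 from a log2 signal of 4.92 ± 0.12 near the lower limit of the tested genes, in an epithelial list with 4 rises and 2 falls of 19 (adjusted p = 0.27). Markers of white blood cells (2 rose, 3 fell of 11, adjusted p = 0.27), luminal cells (4 rose, 1 fell of 11, adjusted p = 0.58) and fibroblasts (1 rose, 0 fell of 5, adjusted p = 0.27) were not called as lists with plus2.

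**Figure D3:**
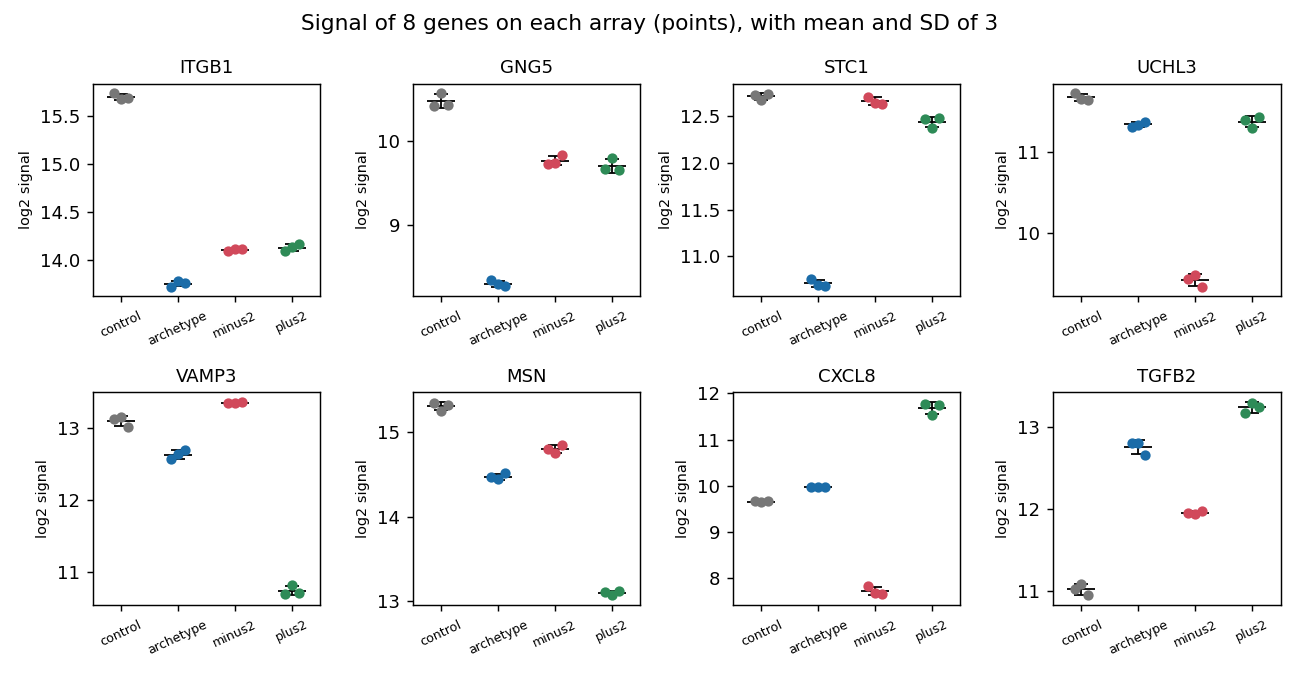
Log2 signal (y axis) of 8 genes on each of the 12 arrays (points), by group (x axis), with the mean and SD of 3 arrays. ITGB1 was lower with all 3 mimics, GNG5 and STC1 lowest with the archetype, UCHL3 lowest with minus2, VAMP3 and MSN lowest with plus2, and CXCL8 lay at 7.72 with minus2 and 11.68 with plus2.

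**Figure D4:**
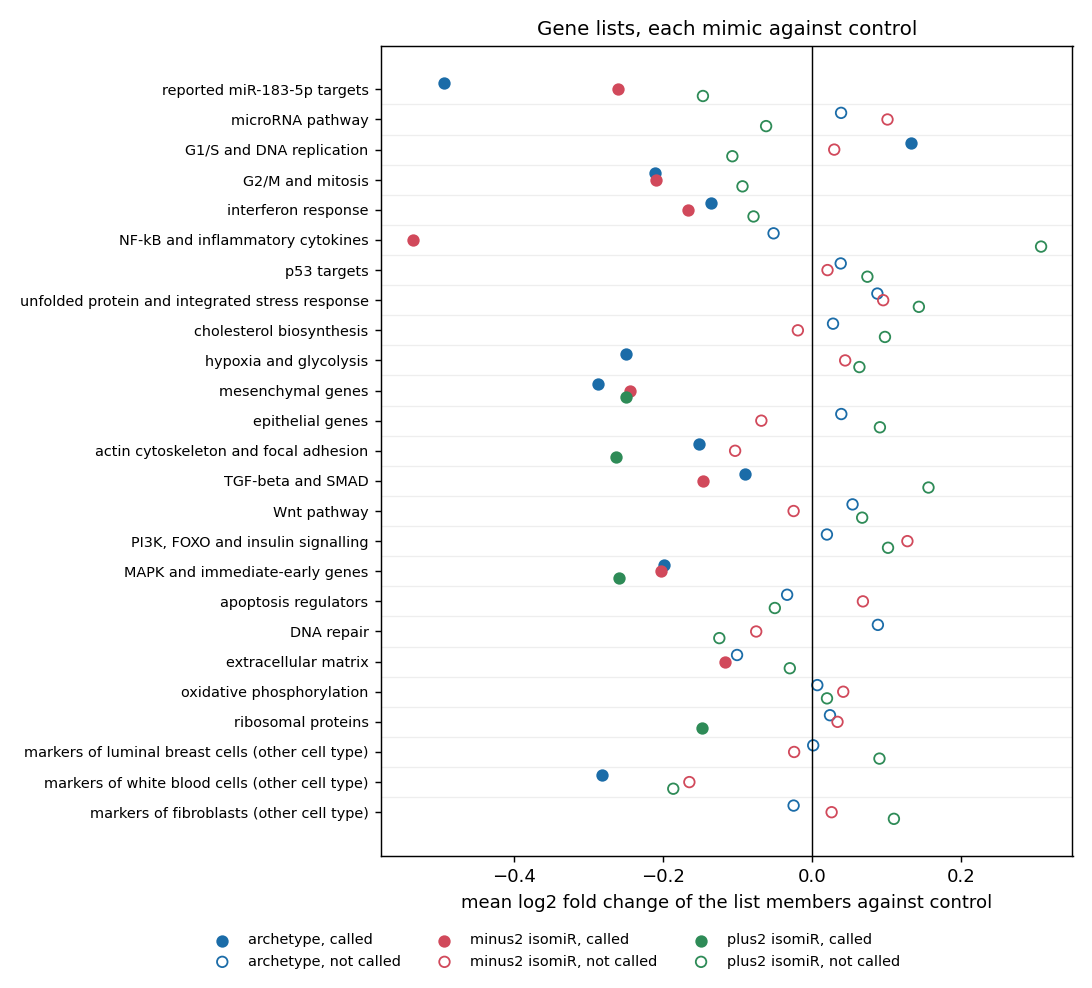
Mean log2 fold change against control (x axis) of the members of each of 25 gene lists (y axis), for each mimic. Filled points are lists called by camera at the preset correlation (10, 8 and 4 lists with the archetype, minus2 and plus2), and open points are lists not called.

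Minus2 and the archetype were compared directly to ask where moving the ends by -2 nucleotides changed the response. STC1 was higher with minus2 than with the archetype by 1.95 ± 0.04 log2 units, as were UHMK1 (1.72 ± 0.06), GINM1 (1.72 ± 0.09), PCLAF (1.64 ± 0.11) and PTP4A2 (1.49 ± 0.04). CXCL8 was lower by -2.25 ± 0.06, with NSA2 (-2.10 ± 0.07), the PP2A methylesterase PPME1 (-2.08 ± 0.08), GDE1 (-1.98 ± 0.11) and UCHL3 (-1.91 ± 0.05). Adjusted p was at most 9.2e-07 among these 10 genes (limma). Of 14940 genes 3629 differed, 1859 higher and 1770 lower with minus2. That majority turned after centring the arrays (1887 and 1926).

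Reported miR-183-5p targets were higher with minus2 than with the archetype in 12 of 19 cases and lower in 2 (12 and 3 adjusted over the list alone), among them PPP2CA (0.84 ± 0.04), BNIP3L (0.82 ± 0.04) and RB1 (0.54 ± 0.06). Camera gave an adjusted p of 0.00014, and adjusted p = 0.17 with an estimated correlation. LRP6 (-0.02 ± 0.04), SOCS6 (0.06 ± 0.05) and PPP2CB (-0.13 ± 0.04) did not pass, which does not show that the mimics act alike on them. Hypoxia and glycolysis genes were higher in 15 of 23 cases and lower in none (15 and 0 alone), with EGLN3 at 0.96 ± 0.08 and hexokinase, HK2, at 0.69 ± 0.08 (camera adjusted p = 1.2e-08, adjusted p = 0.081 with an estimated correlation). NF-kB genes were lower in 14 of 19 cases and higher in 1 (14 and 1 alone), with ICAM1 at -1.22 ± 0.12 and TNFAIP3 at -1.07 ± 0.09 (camera adjusted p = 1.1e-06, adjusted p = 0.17 with an estimated correlation). DNA repair genes were lower in 8 of 20 cases and higher in 1 (9 and 1 alone), with BRCA1 at -0.71 ± 0.07 and PARP1 at -0.53 ± 0.06 (camera adjusted p = 0.0030, adjusted p = 0.93 with an estimated correlation).

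Between plus2 and the archetype, VAMP3 was lower with plus2 by -1.89 ± 0.05 log2 units, with CCNK (-1.71 ± 0.05), SRPRA (-1.65 ± 0.04), SZRD1 (-1.50 ± 0.04) and the ubiquitin ligase gene RNF4 (-1.49 ± 0.06). STC1 (1.73 ± 0.04), CXCL8 (1.71 ± 0.06), ACTBL2 (1.71 ± 0.15), the cytokine gene IL1B (1.51 ± 0.30) and PANK3 (1.46 ± 0.05) were higher. Adjusted p was at most 0.0027 among these genes, the value of IL1B (limma). Of 14940 genes 4316 differed, 1940 higher and 2376 lower with plus2. That majority turned after a further quantile normalisation (2269 and 2181).

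Reported targets were higher with plus2 than with the archetype in 11 of 19 cases and lower in 1 (11 and 2 adjusted over the list alone), among them PPP2CA (1.08 ± 0.04), LRP6 (1.02 ± 0.04) and KIF2A (0.70 ± 0.05). Camera gave an adjusted p of 9.3e-07, and adjusted p = 0.057 with an estimated correlation. Hypoxia and glycolysis genes were higher in 16 of 23 cases and lower in none (16 and 0 alone), with EGLN3 at 1.11 ± 0.08 (camera adjusted p = 1.4e-09, adjusted p = 0.057 with an estimated correlation). TGF-beta and SMAD genes were higher in 14 of 22 cases and lower in 2 (15 and 2 alone), with SMAD6 at 0.56 ± 0.11 (camera adjusted p = 7.8e-06, adjusted p = 0.057 with an estimated correlation). NF-kB genes were higher in 7 of 19 cases and lower in none (10 and 0 alone; camera adjusted p = 0.00038, adjusted p = 0.32 with an estimated correlation).

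G2/M genes were higher with plus2 than with the archetype in 13 of 29 cases and lower in 3 (13 and 3 alone), with CDC25C at 0.43 ± 0.05 (camera adjusted p = 0.0023, adjusted p = 0.69 with an estimated correlation). G1/S and replication genes were lower in 15 of 28 cases and higher in 1 (17 and 2 alone), with the helicase subunit MCM6 at -0.66 ± 0.09 and FEN1 at -0.51 ± 0.07 (camera adjusted p = 1.7e-05, adjusted p = 0.69 with an estimated correlation). Array 3 of plus2 stood apart from the other plus2 arrays on principal component 4 (12.9 against -5.05 and -8.85) and had the lowest signal of MCM6 among them (9.40 against 9.75 and 9.72). Without it the mean change of this list was -0.14 in place of -0.24 (camera adjusted p = 0.00083). Ribosomal protein genes were lower in 12 of 17 cases (13 alone; camera adjusted p = 0.00015, adjusted p = 0.32 with an estimated correlation), and DNA repair genes in 10 of 20 (10 alone; camera adjusted p = 0.00065, adjusted p = 0.68 with an estimated correlation). RPS6 changed by -0.26 ± 0.04 and XRCC2 by -0.75 ± 0.12. Array 3 of plus2 was also the lowest plus2 array for XRCC2 (9.50 against 10.01 and 9.98), and without it the mean change of the DNA repair list was -0.15 in place of -0.21 (camera adjusted p = 0.010).

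By the number of genes called, the isomiRs differed more from each other than either did from the archetype. CXCL8 was 15.6-fold higher with plus2 than with minus2, a log2 difference of 3.96 ± 0.06, followed by NSA2 (2.38 ± 0.07), UCHL3 (1.95 ± 0.05), the TNF receptor family gene TNFRSF9 (1.93 ± 0.14) and PTP4A1 (1.86 ± 0.07). VAMP3 was 6.10-fold lower (-2.61 ± 0.05), with SRPRA (-2.11 ± 0.04), GINM1 (-2.03 ± 0.09), CCNK (-1.84 ± 0.05) and the sialomucin CD164 (-1.83 ± 0.05). Adjusted p was at most 7.3e-07 among these 10 genes (limma). Of 14940 genes 5787 differed, 2659 higher and 3128 lower with plus2. After a further quantile normalisation that majority turned (2972 and 2942). ITGB1 did not pass, with a difference of 0.02 ± 0.04.

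NF-kB and cytokine genes were higher with plus2 than with minus2 in 16 of 19 cases and lower in 1 (16 and 2 adjusted over the list alone), with ICAM1 at 1.32 ± 0.12, TNFAIP3 at 1.32 ± 0.09 and CXCL1 at 1.29 ± 0.09. The camera adjusted p was 9.6e-08, and adjusted p = 0.15 with an estimated correlation. TGF-beta and SMAD genes were higher in 13 of 22 cases and lower in 2 (15 and 2 alone), with TGFBR2 at 1.33 ± 0.04 and TGFB2 at 1.28 ± 0.05 (camera adjusted p = 8.2e-05, adjusted p = 0.15 with an estimated correlation). Ribosomal protein genes were lower in 11 of 17 cases (14 alone; camera adjusted p = 0.0023, adjusted p = 0.80 with an estimated correlation). Reported targets went both ways, with 9 higher and 5 lower of 19 (camera adjusted p = 0.30), and LRP6 was higher with plus2 by 1.04 ± 0.04 while RB1 was lower by -0.51 ± 0.06.

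Against the common control, 1176 genes changed in the same direction with all 3 mimics, 772 up and 404 down. The counts were 697 up and 547 down after centring the arrays and 766 and 519 after a further quantile normalisation. DKK1, CPA4, TGFB2, CRY1 and THBS1 rose with each, and ITGB1, EI24, LAPTM5, LOX and ID1 fell with each. The archetype shared 1917 same-direction calls with minus2 (273 opposite) and 2093 with plus2 (207 opposite), and minus2 and plus2 shared 1665 (756 opposite). Independent lists would share 65.1 rises and 29.5 falls among all 3. In 100 simulations with unrelated effects of the estimated sizes against the same control arrays, all 3 shared 261 to 347 genes. The control arrays were not split between the mimics, so part of the excess over independent lists may come from the shared controls. The covariance of log2 fold changes was 0.0298 for archetype and minus2, 0.0386 for archetype and plus2 and 0.0205 for minus2 and plus2. Simulated covariances in unchanged groups were 0.00398, 0.00399 and 0.00398. The correlations across genes were 0.538, 0.610 and 0.309. In the simulated unchanged groups they were 0.500, 0.501 and 0.500, a value that the shared controls alone set where no group has an effect. Those simulated correlations are therefore no reference for mimics with unrelated effects, and whether the observed ones exceed chance was not read from them. Taking the mean of the mimics, 4204 genes differed from control, 2350 up and 1854 down. After centring the arrays that majority turned (2029 up and 2313 down).

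The list results rest on the preset correlation. With an estimated correlation 2 of the 10 lists called with the archetype stayed called, and none in the other 5 comparisons, while fry, which does not compare a list with other genes, called 10 to 14 lists in each. Other splits of the same 6 arrays called up to 10 lists where the real split called 4 for plus2 against control and 8 for plus2 against the archetype, up to 6 where it called 4 for minus2 against the archetype, and up to 8 where it called 3 between the isomiRs. The arrays carry a feature for the precursor gene but do not measure the mature mimics, and MIR183 lay at a log2 signal of 3.80 ± 0.01 (SD, n = 3) in control and 3.72 ± 0.17 with the archetype, below the signal limit for testing.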

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

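All patterns weighed here were noticed in the data. The tests of dimmer genes, of the shared control arrays, of other scalings of the mimic-specific changes and of genes that changed with another mimic too were chosen only after the result was seen. Leaving CXCL8 out of the NF-kB list was chosen after the list's difference was seen and before the outcome of that test was known. The seed-site test and the estimated correlation were planned, and their use to weigh the mimic-specific falls and the NF-kB list was chosen after these were seen.

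Several genes moved in opposite directions with different mimics, each at least 1.5-fold against control, and the difference itself passed limma's test. Between plus2 and minus2 the log2 difference was 3.96 for CXCL8, -2.11 for SRPRA, 1.70 for CYP2S1, 1.67 for KIF3B, 1.67 for COPS8, -1.61 for EIF4EBP2, -1.58 for PNRC2, -1.52 for RCC2 and 1.504 for MBNL2. It was 1.38 for EDIL3, 1.36 for PPME1, 1.31 for CDK19 and 1.22 for KLRC3. Between minus2 and the archetype it was -2.08 for PPME1, -1.40 for GON7 and -1.38 for MBNL2. Between plus2 and the archetype it was -1.65 for SRPRA and 1.31 for TMEM87B. The adjusted p was at most 0.00018 among these, the value of GON7.

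Transcript clusters without a single gene symbol were not part of the gene-level comparisons. Of 21906 such clusters tested, 466 rose with the archetype, 494 with minus2 and 802 with plus2, while 369, 429 and 918 fell. Their share of calls was 3.81%, 4.21% and 7.85%.

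Changes of at least 1.5-fold against control and against both other mimics are called specific here. Left out were 4 genes shared by all 3 mimics and 6 genes specific to more than 1 mimic. Over the 3 mimics together the specific changes were mostly falls, 225 against 64 rises. The archetype had 12 of these falls and 5 of the rises (two-sided binomial p = 0.14), so a majority of falls was not shown for it alone. Of the 289 specific genes, 15 also changed at least 1.5-fold in the same direction with another mimic. By contrast, changes of at least 1.5-fold shared by all 3 mimics were mostly rises, 73 against 31 falls (Fisher's exact test, odds ratio 8.23, two-sided p = 4.7e-18, and genes are not independent). Against signal level or 1 array as the whole cause, the lower 95% bound of the odds ratio was 7.50 among genes brighter than the median and at least 4.08 without each array in turn, and the odds ratio was 7.35 after centring, 6.81 after a further quantile normalisation and 8.90 without those 15 genes. Among dimmer genes the pattern was not seen, with 11 specific falls against 30 rises and an odds ratio of 1.10 (0.284 to 4.79), so it holds for brighter genes and a part of signal level stays open. Repression through each mimic's own seed may account for the specific falls, but 0 files of transcript sequence with 3′ untranslated regions were used, so this stays open.

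In all, 1176 genes changed in the same direction with all 3 mimics. With unrelated effects of the estimated sizes and shared control arrays, 100 simulations gave at most 347 such genes. The simulated archetype, minus2 and plus2 had means of 4805.9, 5439.4 and 6064.3 calls, more than the real 3669, 4388 and 5020. That maximum argues against chance values of those arrays, independent between genes, as the whole cause, though not for a part of the genes. Noise was drawn apart for each gene, so a deviation of the control arrays common to many genes was not tested. An effect of the control oligonucleotide could be the source and cannot be told apart from a shared response, since the labels name no untransfected sample. Of the 1176 genes 58.8% differed between the mimics, but so did 44.5% of all tested genes, so the limit of 5% set in advance for that share decides nothing, and the other 484 genes were not shown to differ. A response to the 18 shared bases was not tested.

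The NF-kB and cytokine list was higher with plus2 than with minus2 by a mean of 0.84 log2 units. Without any 1 array the largest adjusted p was 2.9e-07 (camera), and without CXCL8 it was 1.7e-06 with a mean of 0.67, which argues against either as the whole cause. Members that vary together from array to array stay open as a possible explanation for the list call, with an adjusted p of 0.147 at an estimated correlation. The difference in sequence between the mimics, named by the design, is a biological explanation that was not tested further.

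With 3 against 3 arrays there are 10 splits, too few for a share under 0.05. In each of the 6 comparisons 1 split, the real one, gave as many genes, with real counts of 3669, 4388, 5020, 3629, 4316 and 5787 and a highest other of 0; mixing groups also widens the shared spread. For lists, the number of splits with as many was 1 for the archetype against control (real 10, highest other 7), 1 for minus2 (8 and 7), 6 for plus2 (4 and 10), 2 for minus2 against the archetype (4 and 6), 4 for plus2 against the archetype (8 and 10) and 7 between the isomiRs (3 and 8). Among 100 splits of all arrays, 1 split, the real one, gave as many genes for the mean of the mimics (real 4204, highest other 1787). The same held for any difference among the 4 groups (1 split, 7726 and 1221) and for the calls shared by all 3 mimics (1 split, 1176 and 941). These splits argue only against the case that no group differs. They mix groups, which widens the spread, and for the shared calls none kept the groups whole with another group as control. They therefore do not test the sharing itself.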

How the results depend on the processing

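Leaving CXCL8 out of the NF-kB list, and the other fold limits, scalings and gene sets for mimic-specific changes, were chosen only after the data were seen (for CXCL8, before the outcome without it was known). For 646 gene results, 14698 of 15474 alternative values kept direction and call, 773 lost the call, 3 gained it and 0 reversed. These are genes named by the rule, nearly all called and many picked for large changes. Some alternatives, such as a looser threshold, could hardly lose a call. The share kept therefore does not describe gene calls in general. For 45 list results, 672 of 721 kept both and 49 lost the call. With an estimated correlation the lists called were 2 with the archetype and 0 with minus2, with plus2, in each comparison between mimics and for the mean of the mimics. With fry they were 13 with minus2, 14 with plus2, 11 for minus2 against the archetype, 14 for plus2 against the archetype and 14 between the isomiRs. Without a filter 6 lists were called between the isomiRs. The cause was not tested. At 1.5-fold or more, fewer genes pass by construction: 414, 489 and 721 against control, 427, 393 and 962 between mimics, 322 for the mean, 171, 223 and 155 shared by pairs of mimics and 104 by all 3. At an adjusted p under 0.01 they were 2299 and 2855 for the archetype and minus2, 2271 and 2769 for minus2 and plus2 against the archetype, 2662 for the mean, 1114, 1325 and 994 shared by pairs and 705 by all 3.

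Without each array in turn the counts ranged from 2926 to 4077, 3557 to 4774 and 4312 to 4948 against control, 2809 to 4042, 3532 to 4228 and 4940 to 5728 between mimics, 3157 to 4557 for the mean, 7009 to 7752 for any difference and 946 to 1277 for calls shared by all 3. Lists called with plus2 ranged from 4 to 7 and between the isomiRs from 3 to 5, the highest values being those without plus2 replicate 2. In these fits a group of 2 arrays shares the spread of the others. With a replicate block the counts against control were 3925, 4651 and 5286, and 1276 genes were shared by all 3. Of 18 same-numbered pairs 9 correlated over 0.1 (-0.04 to 0.27), and 9 of 12 arrays correlated best with their own number, a hint from the data of some shared deviation. The numbers were not treated as pairs because the labels give them no meaning and not every pair was over 0.1. Array signal near background limits dim genes. The planned seed-site test and its alternatives (6mer, 8mer and control 7-mers) were not run, because no 3′ untranslated sequence was used here.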

Other observations

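The gene families below were chosen after their values were seen, and no test of them as groups was planned. Of 9 tested pregnancy-specific glycoprotein genes, secreted immunoglobulin-family proteins best known from placenta, 9 rose with the archetype (median log2 change 1.21, from 0.60 to 1.58), 8 with minus2 (median 0.60) and 9 with plus2 (median 0.85). Those counts were the same after centring the arrays and after a further quantile normalisation. Family members are near-identical in sequence, so their signals are not independent. Control signals were low, from 4.35 for PSG11 to 5.56 for PSG4, and a signal near or below the limit of 4.54 set on the mean of all arrays is not shown to be above background. The sizes of these changes are therefore uncertain. TMSB4X, an actin monomer-binding peptide gene, and its 2 processed copies fell with the archetype (median -1.37) and with plus2 (median -1.08). The copies are near-identical to TMSB4X in sequence, so the 3 signals are not separate evidence. With minus2 none of the 3 was called (median -0.15), although 2 of them fell after centring. Of 24 replication-dependent histone genes, 7 fell with the archetype, 6 with minus2 and 12 with plus2, against 0, 1 and 1 that rose, and these falls numbered 7, 7 and 12 after centring and 5, 5 and 11 after a further quantile normalisation.

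Changes of at least 1.5-fold against control and against both other mimics were also collected after the values were seen. The 4 genes shared by all 3 mimics and the 6 specific to more than 1 mimic were left out here too. The archetype had 5 such rises and 12 falls, minus2 10 and 94, and plus2 49 and 119. Among the archetype's were the rises of C2CD3 (1.66 ± 0.06, SE) and of the ubiquitin ligase gene NEDD4L (1.10 ± 0.06). With minus2 and plus2 the log2 changes were 0.80 and 0.54 for C2CD3, and 0.47 and 0.40 for NEDD4L. Both changes were thus larger with the archetype but not confined to it. The odds ratio of falls among specific against shared genes was 3.62 with a lower fold limit and 14.4 with a limit of 2-fold.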
